A study of Homo sapiens with 12 samples.

How the data were processed

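RNA with poly(A) tails from OCI-AML3 cells, unedited or labelled CDKN2A gRNA and kept for 7 days in vehicle (DMSO) or 1 µM WM-1119, was sequenced as single 75 bp reads with a library kit that does not mark strand, per the labels. The 12 libraries form 4 groups of 3 replicates, and the groups were taken from the labels. The labels do not say whether replicates were separate cultures or separate edits, so every p-value here measures the spread between libraries only. The deposited table holds RSEM expected counts per gene, not scaled for depth or length, with 1 column per library. Per the submitters' processing notes the tools were cutadapt 1.11, STAR 2.5.2a, RSEM 1.2.30 and edgeR with the build GRCh37, and no role, strand setting or annotation release is given. Of the 33538 gene IDs in the table, 33456 (99.8%) are also in GENCODE 29, an annotation of another build, so the build behind the counts is uncertain and no coordinates are given. Symbols were taken from the table, in which 26 entries share a symbol with another. Because strand was not recorded, reads from exons that a gene shares with an antisense or overlapping partner cannot be assigned with certainty; in GENCODE 29, the genes named that share exons with another gene tested were BCL2L11, CDKN2A, CEBPB, CHEK1, DCK, ETV5, HMGCS1, HOXA9, HOXA13, HOXB2, HOXB3, IDI1, KAT7, LYZ, PRIM1, RRM2, SATB1, SDHD, SERPINB10, SHMT2, SPTB and STARD4, whose values are uncertain in that respect.

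Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's filterByExpr with its defaults on the 4 groups (14489 of 33538), libraries were scaled with TMM factors, and 1 quasi-likelihood model (glmQLFit, robust) with a mean per group was fitted to all 12 libraries. No unit, covariate or block other than the group entered this model. Totals of 10586117 to 18127218 counts per library mean that 1 count is 0.0546 to 0.0969 CPM. The 5 contrasts tested with glmQLFTest were WM-1119 against vehicle in unedited cells and in cells labelled CDKN2A gRNA, the difference of these 2 effects (gRNA-labelled minus unedited), and gRNA-labelled against unedited cells under vehicle and under WM-1119. P-values were adjusted with the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. CPM values were computed with edgeR on the TMM-scaled totals, log2 fold changes are given with their SE, and levels as mean ± SD of 3 libraries. The SE of a gene's log2 fold change is its absolute value over the square root of the quasi-likelihood F statistic. It therefore rests on the spread pooled over all 12 libraries and moderated across genes.

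The model, the contrasts, the gene lists, the rule for named genes and most alternatives were set before the data were examined. The named genes were, for each contrast, the 10 with the largest rise and the 10 with the largest fall (5 and 5 for the difference) among those past the threshold with a mean of at least 5 CPM in the higher group and all 3 libraries of 1 group above all 3 of the other (for the difference, at least 5 CPM in any group and no rule on overlap). To these were added up to 4 members of each list with the smallest adjusted p, and always CDKN2A, CDKN2B, CDKN1A, MDM2, KAT6A, KAT6B, KAT7, MEIS1, HOXA9, MYC, ITGAM, BCL2, MCL1 and BCL2A1. Some were left out of the text for length or because they lay near 0, and a few genes and 1 list are not reported here. Of 237 called results for such genes in the 4 contrasts between 2 groups, 235 had all 3 libraries of 1 group above all 3 of the other. The rule itself required this of part of them, and passing the threshold favours it in the rest. Chance gives it for 10% of unselected genes with 3 against 3, so that rate is no fair comparison for called genes. The 2 others were MEIS1 and ITGAM between genotypes under WM-1119.

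The 31 gene lists had 843 entries, of which 836 were matched by symbol and 6 by an older symbol, with 1 unmatched. Among them were G1/S and DNA replication, G2/M and mitosis, DNA repair and checkpoint genes, cell cycle inhibitors, BCL2 family and apoptosis, senescence-associated secretory, HOX and MEIS1, stem and progenitor, monocyte and macrophage maturation and neutrophil granule genes. Further ones were MYST acetyltransferases and partners, MYC targets and ribosome biogenesis, cytosolic ribosomal protein, interferon-stimulated, antigen presentation, NF-kB and immediate early, amino acid and integrated stress response, endoplasmic reticulum chaperone and heat shock, cholesterol synthesis, mitochondrial respiratory chain, glycolysis and hypoxia, nucleoside analogue and drug transport and histone genes. Others were the protein-coding genes of the mitochondrial genome, genes near CDKN2A on chromosome 9, and erythroid, megakaryocyte, lymphoid, basophil, eosinophil and mast cell, and epithelial and fibroblast markers. For each list the members measured, those past the threshold over all genes and those past it when adjusted over the list alone were counted. The 28 lists with at least 5 measured members were tested as sets with camera (limma 3.58.1) at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, which asks whether a set moves on balance and compares it with no other genes; p-values of set tests were adjusted over the lists of a contrast.

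The pipeline was tested on simulated data with known fold changes drawn from the real means and library sizes. Only a small share of genes was changed, in a single group, around a mean shared by all 4 groups. No genotype effect and no library that stands apart were simulated, so these rates need not hold for the real contrasts. For WM-1119 in unedited cells (14313 genes) it recovered 47 of 67 genes changed 1.5-fold (70.1%), 48 of 67 changed 2-fold (71.6%) and 60 of 66 changed 4-fold (90.9%), and called 14 of 14259 unchanged genes. For the difference of effects (14292 genes) it recovered 31 of 67 (46.3%), 48 of 67 (71.6%) and 55 of 66 (83.3%) and called 5 of 14259 unchanged genes.

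The alternatives were DESeq2 1.42.0 median-ratio factors in edgeR, the DESeq2 Wald test, no low-count filter, a filter of at least 5 CPM in at least 3 libraries, the fit without the robust option, the groups of a contrast alone, the replicate number as a block, and each of the 12 libraries left out in turn. A further 2 alternatives were chosen after seeing the data: all libraries thinned to the smallest total, and a fit without 2 libraries, the unedited WM-1119 replicate 3 (lowest total) and the gRNA-labelled WM-1119 replicate 2 (high in RNAs without a poly(A) tail). Other splits of the same libraries into groups were also fitted. No sample column was left out.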

Results

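The series measured polyadenylated RNA in OCI-AML3, a human acute myeloid leukaemia cell line that carries a mutated NPM1 gene. Cells were either unedited or labelled as carrying a CDKN2A guide RNA (gRNA), which directs gene editing to the gene of that name. Each kind of cell was kept for 7 days in vehicle (DMSO) or in 1 µM WM-1119, an inhibitor of the lysine acetyltransferases KAT6A and KAT6B. CDKN2A encodes cell cycle inhibitors, and the series text asks how cells with and without its depletion differ in gene expression under the compound. The 12 libraries form 4 groups of 3. Totals of expected counts per library ran from 10586117 to 18127218. They were lowest in the unedited WM-1119 replicate 3 (10586117), the gRNA-labelled vehicle replicate 2 (11948779) and the gRNA-labelled WM-1119 replicate 2 (14906530), and the others held at least 17286867. Of the 33538 genes listed, 14489 had enough counts to be tested. Levels are given in CPM, counts scaled to the size of the library. Changes are log2 fold changes ± SE from the model over all 12 libraries, with 3 per group. A gene is said to have risen or fallen where edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested passed 0.05.

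CDKN2A (ENSG00000147889), the gene the guide targets, was at 22.9, 24.4 and 26.5 CPM in the unedited vehicle libraries and at 36.8, 37.6 and 38.2 CPM in the vehicle libraries labelled CDKN2A gRNA. Under WM-1119 it was at 60.1, 55.5 and 42.9 CPM in the unedited libraries and at 103, 107 and 93.7 CPM in those labelled CDKN2A gRNA. Its mRNA was thus 1.52-fold higher in the gRNA-labelled libraries under vehicle (adjusted p = 0.0037) and 1.90-fold higher under WM-1119 (adjusted p = 4.4e-06), the opposite of a lowered transcript. Without strand, its reads cannot be told from those of CDKN2B-AS1, an antisense gene that shares exons with it and had a mean of 1.06 CPM over all libraries, against 54.1 CPM. Editing breaks DNA and need not lower the mRNA, so these levels do not measure loss of protein, and they do not check the genotype labels in the direction a knockdown would. Every direction between genotypes given here therefore follows the labels alone. GATA2 (ENSG00000179348) separated the genotypes in all 12 libraries, whereas CDKN2A did so only within a treatment. Its group means were 3.48 and 4.02 CPM in unedited libraries and 18.8 and 27.6 CPM in gRNA-labelled ones. An antisense gene lies in the same place, but shares no exons with it in GENCODE 29.

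**Figure D1:**
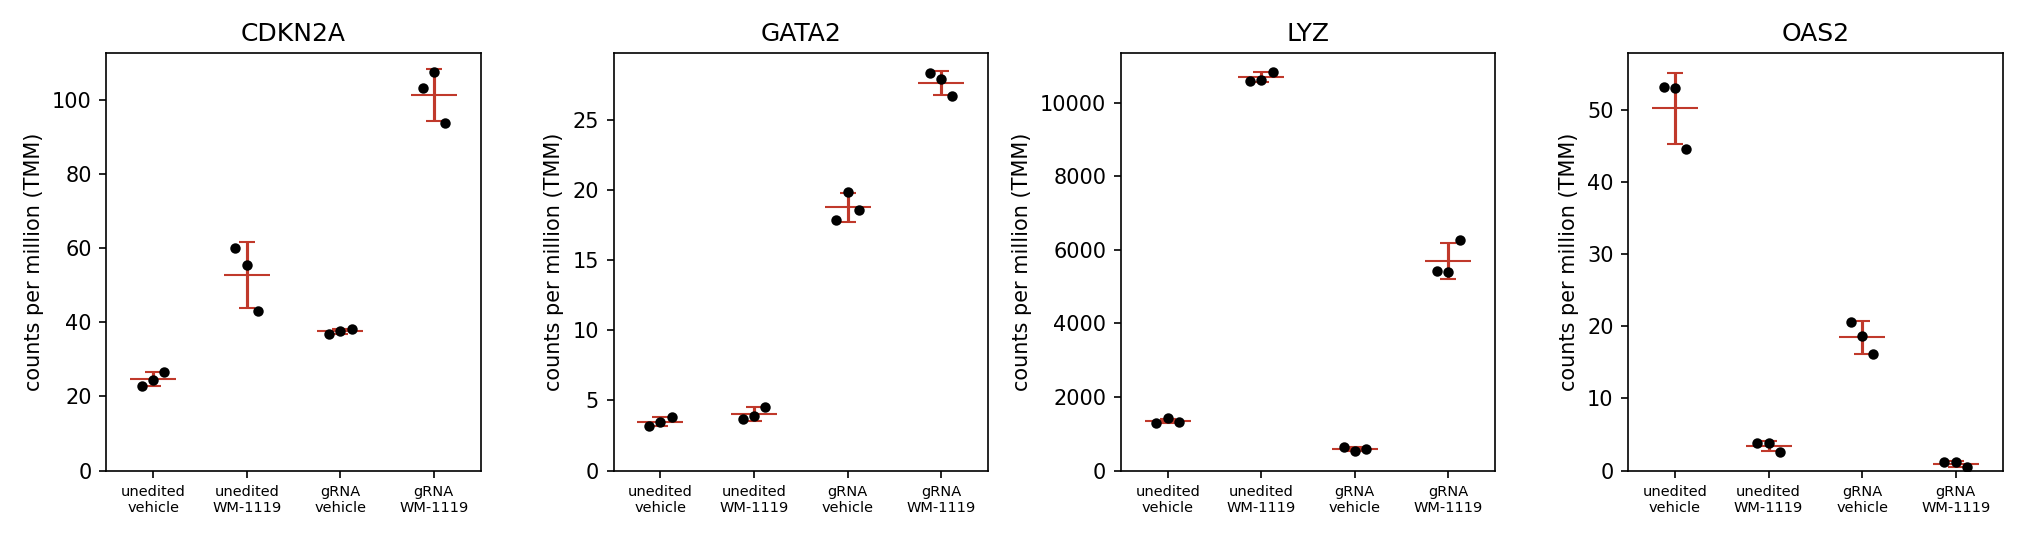
Level of CDKN2A, GATA2, LYZ and OAS2 in each of the 12 libraries, in CPM scaled with TMM factors, by group. Points are libraries, the long red line is the mean of 3 and the short lines its SD. CDKN2A rose with WM-1119 and was higher in the libraries labelled CDKN2A gRNA (labelled gRNA on the axis), GATA2 followed the genotype label, LYZ rose and OAS2 fell with WM-1119 in both genotypes.

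In unedited cells, 7 days of WM-1119 raised genes such as LYZ, S100A8 and S100A9 and lowered genes such as OAS2 and OAS3. LYZ, which encodes lysozyme of monocytes and granulocytes, rose 7.92-fold (log2 2.99 ± 0.07), to 1.04 to 1.06% of all counts. S100A8 and S100A9, the subunits of calprotectin, rose by 3.31 ± 0.20 and 3.18 ± 0.25 on the log2 scale. OAS2 and OAS3, sensors of double-stranded RNA that interferon induces, fell 14.4-fold and 18.9-fold (log2 -3.85 ± 0.16 and -4.24 ± 0.17). CDKN2A rose 2.16-fold (adjusted p = 9.6e-07). LYZ shares its locus with an antisense gene whose reads could not be separated from it. In all, 2525 genes rose and 2712 fell, of which 332 rose and 402 fell at least 2-fold.

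Among 35 monocyte and macrophage maturation genes measured in unedited cells, 16 rose and 5 fell with WM-1119, or 17 and 7 when adjusted over the list alone. The list rose as a set (camera adjusted p = 1.2e-05), a call that was lost with an estimated correlation (adjusted p = 0.391 with an estimated correlation). Besides LYZ and calprotectin, the signalling adaptor TYROBP rose by 1.62 ± 0.14, the integrin ITGAM, which encodes CD11b, by 2.06 ± 0.27 and the G-CSF receptor CSF3R by 1.22 ± 0.07. FCGR2B, the inhibitory receptor for immunoglobulin G, went the other way (-3.89 ± 0.28). Neutrophil granule genes rose in 11 of 13 and fell in 1, the same counts when adjusted over the list alone (camera adjusted p = 9.9e-08, adjusted p = 0.243 with an estimated correlation). The granule proteases PRTN3 and ELANE rose 2.65-fold and 1.56-fold, and AZU1 rose 1.94-fold. Among the 10 largest rises were also those of the serpin SERPINB10 (3.61 ± 0.28), the platelet-activating factor receptor PTAFR (2.90 ± 0.23), the prolactin receptor PRLR (2.70 ± 0.24) and the cytidine deaminase CDA (2.66 ± 0.22). SERPINB10 overlaps SERPINB2, so its value is uncertain.

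Interferon-stimulated genes fell in 30 of 35 members and rose in 0 in unedited cells under WM-1119, also 30 when adjusted over the list alone, with a median log2 fold change of -1.51. This set test (camera adjusted p = 5.7e-45) held with an estimated correlation (adjusted p = 0.019 with an estimated correlation), which happened in 2 further comparisons for this list and in none for any other list. The 2 were WM-1119 in gRNA-labelled cells and the genotypes under vehicle. MX1 and IFI6, both antiviral effectors, fell as well (-3.10 ± 0.16 and -2.64 ± 0.14). The interferon-induced IFI27 went from 11.6 ± 0.477 CPM (SD, n = 3) to 0.285 ± 0.0552 CPM, too close to 0 for a fold.

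Of 40 G1/S and DNA replication genes 32 fell and 0 rose in unedited cells under WM-1119, and 36 fell when adjusted over the list alone, with a median of -0.45. The replication licensing factor CDT1 fell 2.16-fold, and on the log2 scale the ribonucleotide reductase subunit RRM2 fell by 0.90 ± 0.09 and the helicase subunit MCM5 by 0.59 ± 0.06. Of 35 G2/M and mitosis genes 32 fell and 0 rose, 33 when adjusted over the list alone. They included CCNB1 (-0.57 ± 0.05), CDK1 (-0.54 ± 0.07) and the proliferation marker MKI67 (-0.60 ± 0.07). DNA repair and checkpoint genes fell in 21 of 30 and rose in 2, the same when adjusted over the list alone, with BARD1 at -0.85 ± 0.09 among them. The 3 lists fell as sets (camera adjusted p = 2.7e-15, 1.2e-13 and 3.5e-07). Each call was lost with an estimated correlation (adjusted p = 0.243 with an estimated correlation for each). Among 13 cell cycle inhibitors, 2 rose and 3 fell, or 3 and 5 when adjusted over the list alone. The antiproliferative gene BTG1 rose by 0.84 ± 0.06 and CDKN1B fell by 0.45 ± 0.06, while CDKN1A was at 0.04 ± 0.15 (adjusted p = 0.87). That list's median was -0.10, its mean 0.04 and its set test pointed up without a call (camera adjusted p = 0.78).

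Amino acid and integrated stress response genes, most of them targets of the transcription factor ATF4, fell in 28 of 30 and rose in 1 in unedited cells, the same when adjusted over the list alone. Their median was -0.76 (camera adjusted p = 1.6e-14, adjusted p = 0.296 with an estimated correlation). The cystathionine synthase CBS fell by 0.69 ± 0.07, the mitochondrial serine enzyme SHMT2 by 0.53 ± 0.05 and the stress sensor SESN2 by 0.92 ± 0.11. Glycolysis and hypoxia genes fell in 14 of 27 and rose in 1, with 17 and 1 when adjusted over the list alone (camera adjusted p = 1.2e-05, adjusted p = 0.437 with an estimated correlation). Among them were the glucose transporter SLC2A1 (-0.78 ± 0.09) and BNIP3 (-0.84 ± 0.07). Senescence-associated secretory genes fell in 13 of 28 and rose in 2, also when adjusted over the list alone (camera adjusted p = 0.0080, adjusted p = 0.391 with an estimated correlation). The collagenase MMP1 fell by 4.03 ± 0.26 and the chemokine CXCL1 by 0.89 ± 0.11, whereas the chemokine CCL5 rose by 0.64 ± 0.06. With only genes of at least 5 CPM in 3 libraries kept, 8 of those secretory genes fell.

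All 13 protein-coding genes of the mitochondrial genome rose in unedited cells under WM-1119, also when adjusted over the list alone (camera adjusted p = 3.1e-04, adjusted p = 0.601 with an estimated correlation). MT-CO1 rose by 0.64 ± 0.13. The mitochondrial share of counts was 7.84 to 10.01% in these 3 libraries and 5.79 to 7.30% in the other 9. Without the unedited vehicle replicate 3, 8 of the 13 rose, and without the unedited WM-1119 replicate 3, which had the lowest total of counts, 7 rose. Nuclear genes of the respiratory chain rose in 15 of 31 and fell in 0, with 15 and 1 when adjusted over the list alone (camera adjusted p = 0.016, adjusted p = 0.391 with an estimated correlation). SDHD (0.38 ± 0.06) and NDUFB5 (0.37 ± 0.07) were among them.

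In unedited cells, the anti-apoptotic gene BCL2 fell 1.73-fold (-0.79 ± 0.06), and the pro-apoptotic genes BCL2L11 and PMAIP1 fell by 0.43 ± 0.06 and 0.83 ± 0.11. Of 24 BCL2 family and apoptosis genes 2 rose and 4 fell, also when adjusted over the list alone, without a set call (camera adjusted p = 0.27). MYC fell by 0.44 ± 0.08. Of 34 MYC targets and ribosome biogenesis genes 14 fell and 2 rose, the same when adjusted over the list alone (camera adjusted p = 0.040, adjusted p = 0.391 with an estimated correlation). Examples were NCL (-0.40 ± 0.06) and NOLC1 (-0.49 ± 0.07). Of 20 HOX and MEIS1 genes 8 fell and 2 rose, or 8 and 3 when adjusted over the list alone (camera adjusted p = 0.19). HOXA13 fell by 0.76 ± 0.07 and MEIS1 by 0.48 ± 0.10, and HOXA9 was at -0.04 ± 0.08 (adjusted p = 0.75). KAT6A, one of the targets of the compound, fell by 0.27 ± 0.09 (adjusted p = 0.021). Its call was lost without the unedited vehicle replicate 2, the unedited vehicle replicate 3 or the unedited WM-1119 replicate 2 (adjusted p = 0.062, 0.099 and 0.098, against 0.0040 to 0.099 over all alternatives).

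The other lists moved less evenly in unedited cells under WM-1119. Stem and progenitor genes rose in 5 of 17 and fell in 9, or 6 and 9 when adjusted over the list alone (camera adjusted p = 0.27). The chromatin organiser SATB1 was at -0.55 ± 0.05 and RUNX1 at 0.55 ± 0.05. MYST acetyltransferases and partners rose in 2 of 21 and fell in 5 (camera adjusted p = 0.32). Nucleoside analogue and drug transport genes rose in 2 of 18 and fell in 7 (camera adjusted p = 0.27), and antigen presentation genes rose in 5 of 17 and fell in 3 (camera adjusted p = 0.69). These 3 lists had the same counts when adjusted over the list alone. NF-kB and immediate early genes rose in 7 of 32 and fell in 5, also when adjusted over the list alone (camera adjusted p = 0.99). Endoplasmic reticulum chaperone and heat shock genes rose in 6 of 25 and fell in 4, or 7 and 4 when adjusted over the list alone (camera adjusted p = 0.78). Cytosolic ribosomal protein genes rose in 2 of 71 and fell in 7, or 0 and 0 when adjusted over the list alone (camera adjusted p = 0.47). Falls of ribosomal protein genes numbered 4 when any 1 of the 3 unedited vehicle libraries was left out. They numbered 16 without the unedited WM-1119 replicate 1 and 2 without its replicate 2 or replicate 3, so no direction is read from them. MYST falls numbered 3 without the unedited vehicle replicate 3 or the unedited WM-1119 replicate 2. Falls in the NF-kB list numbered 3 without the unedited vehicle replicate 2, and those of chaperone genes 2 without the unedited vehicle replicate 3. Some list counts of 3 or fewer also moved by more than 1.5-fold with 1 library left out. The antigen presentation list had a median of -0.04 and a mean of -0.01 with a test that pointed up, and the NF-kB list a median of 0.02 and a mean of -0.05. Histone genes rose in 1 of 19 and fell in 3, also when adjusted over the list alone (camera adjusted p = 0.28), with the linker histone H1F0 at -1.99 ± 0.16. Of 8 genes near CDKN2A on chromosome 9, 1 rose, CDKN2A itself, and 3 fell, or 2 and 3 when adjusted over the list alone (camera adjusted p = 0.99). Markers of other lineages were mostly too low to test. Of 18 erythroid genes 3 were measured, of which 1 rose and 2 fell, and of 14 basophil, eosinophil and mast cell genes 2, without a call. Of 19 lymphoid genes 4 were measured, and EBF1 (-2.87 ± 0.23) and IL7R (-2.29 ± 0.22) fell. Their counts were the same when adjusted over the list alone. Megakaryocyte genes rose in 2 of 6 and epithelial and fibroblast genes fell in 2 of 6, also when adjusted over the list alone (camera adjusted p = 0.27 and 0.47).

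In cells labelled CDKN2A gRNA, WM-1119 also raised LYZ and lowered OAS2 and OAS3. LYZ rose 9.81-fold (3.29 ± 0.07), PRLR 10.6-fold (3.41 ± 0.25), PTAFR 6.06-fold (2.60 ± 0.23), and OAS2 and OAS3 fell 20.4-fold and 19.7-fold (-4.35 ± 0.21 and -4.30 ± 0.21). CDKN2A rose 2.70-fold (adjusted p = 7.8e-08) and CDKN1A, which encodes the CDK inhibitor p21, rose 1.84-fold (0.88 ± 0.15). In all, 1239 genes rose and 1362 fell, of which 179 rose and 312 fell at least 2-fold. The germline cyclin gene CCNA1 (3.82 ± 0.33), the lectin receptor CD209 (2.69 ± 0.28), the prostaglandin receptor PTGER2 (2.19 ± 0.20) and the lipase LPL (2.09 ± 0.13) were among the 10 largest rises. MMP1 (-3.96 ± 0.23), FCGR2B (-3.35 ± 0.25), the netrin receptor UNC5B (-3.27 ± 0.18) and the granzyme GZMA (-3.12 ± 0.57) were among the 10 largest falls.

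Of 35 interferon-stimulated genes 30 fell and 1 rose in gRNA-labelled cells, the same when adjusted over the list alone, with a median of -1.20 (camera adjusted p = 2.9e-41, adjusted p = 0.020 with an estimated correlation). That median is the same with 3 members that had no count in the WM-1119 group set to a floor of 3 counts per library. OAS1 fell by 3.57 ± 0.34 and IFI6 by 2.95 ± 0.18. Cholesterol synthesis genes rose in 16 of 23 and fell in 0, and 20 rose when adjusted over the list alone (camera adjusted p = 5.7e-13, adjusted p = 0.143 with an estimated correlation). The mevalonate enzymes MVD and IDI1 rose by 0.74 ± 0.08 and 0.48 ± 0.07, and the sterol carrier STARD4 by 0.63 ± 0.07. In unedited cells 6 members of that list rose and 2 fell, also when adjusted over the list alone, without a set call (camera adjusted p = 0.30).

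G1/S and DNA replication genes rose in 1 and fell in 2 of 40 in gRNA-labelled cells, or 1 and 0 when adjusted over the list alone, with a median of -0.04 and no set call (camera adjusted p = 0.65). G2/M and mitosis genes fell in 20 of 35, and 22 when adjusted over the list alone, and rose in 0 (camera adjusted p = 6.6e-08, adjusted p = 0.523 with an estimated correlation). CCNB1 was at -0.38 ± 0.05, TPX2 at -0.34 ± 0.05 and TOP2A at -0.34 ± 0.06. Without the gRNA-labelled WM-1119 replicate 2, 13 of them fell. Amino acid and integrated stress response genes rose in 1 and fell in 1 of 30, also when adjusted over the list alone (camera adjusted p = 0.65). That list's median was 0.03 and its mean -0.01. DNA repair and checkpoint genes rose in 1 and fell in 2 of 30, also when adjusted over the list alone (camera adjusted p = 0.65). Among 13 cell cycle inhibitors 4 rose and 3 fell, or 5 and 3 when adjusted over the list alone (camera adjusted p = 0.076, median -0.03 and mean 0.22). BTG1 rose by 0.87 ± 0.06 and CDKN1B fell by 0.41 ± 0.06.

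HOX and MEIS1 genes fell in 8 of 20 and rose in 0 in gRNA-labelled cells, with 10 falling when adjusted over the list alone (camera adjusted p = 3.4e-07, adjusted p = 0.523 with an estimated correlation). HOXB2 fell by 1.05 ± 0.12, MEIS1 by 0.87 ± 0.11, HOXB3 by 0.86 ± 0.11 and HOXA13 by 0.80 ± 0.07, and HOXA9 was at -0.12 ± 0.08 (adjusted p = 0.30). Monocyte and macrophage maturation genes rose in 9 of 35 and fell in 6, or 13 and 6 when adjusted over the list alone (camera adjusted p = 0.010, adjusted p = 0.794 with an estimated correlation). The transcription factor CEBPB (0.60 ± 0.05), CSF3R (0.80 ± 0.07) and ITGAM (1.34 ± 0.29) rose. The monocyte rises numbered 14 without the unedited WM-1119 replicate 1 or replicate 3. Neutrophil granule genes rose in 4 of 13 and fell in 1, also when adjusted over the list alone (camera adjusted p = 0.082). Their rises numbered 2 without the gRNA-labelled vehicle replicate 2, vehicle replicate 3 or WM-1119 replicate 3. NF-kB and immediate early genes rose in 11 of 32 and fell in 3, or 11 and 5 when adjusted over the list alone (camera adjusted p = 0.010, adjusted p = 0.724 with an estimated correlation). JUND rose by 0.68 ± 0.07 and ETV5 by 0.69 ± 0.11. The rises in that list numbered 6, 7, 6 and 6 without the gRNA-labelled vehicle replicate 1, vehicle replicate 2, WM-1119 replicate 1 and WM-1119 replicate 2. BCL2L11 fell by 0.56 ± 0.06 and BCL2 by 0.25 ± 0.06, and MYC was at -0.04 ± 0.08 (adjusted p = 0.77). Histone genes rose in 2 of 19 and fell in 2, or 4 and 3 when adjusted over the list alone (camera adjusted p = 0.93). Their median of 0.66 was -0.06 without the gRNA-labelled WM-1119 replicate 2, a library high in RNAs that carry no poly(A) tail.

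The effects of WM-1119 in unedited and in gRNA-labelled cells, which share no library, correlated across the 14489 genes (Pearson r = 0.583, Spearman rho = 0.535), a description across genes that are not independent replicates. In both, 838 genes rose, against 216 for independent lists, and 965 fell, against 255, while 23 went opposite ways, against 469. Without the unedited WM-1119 replicate 1 or the gRNA-labelled WM-1119 replicate 3, r was 0.480 and 0.479.

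**Figure D2:**
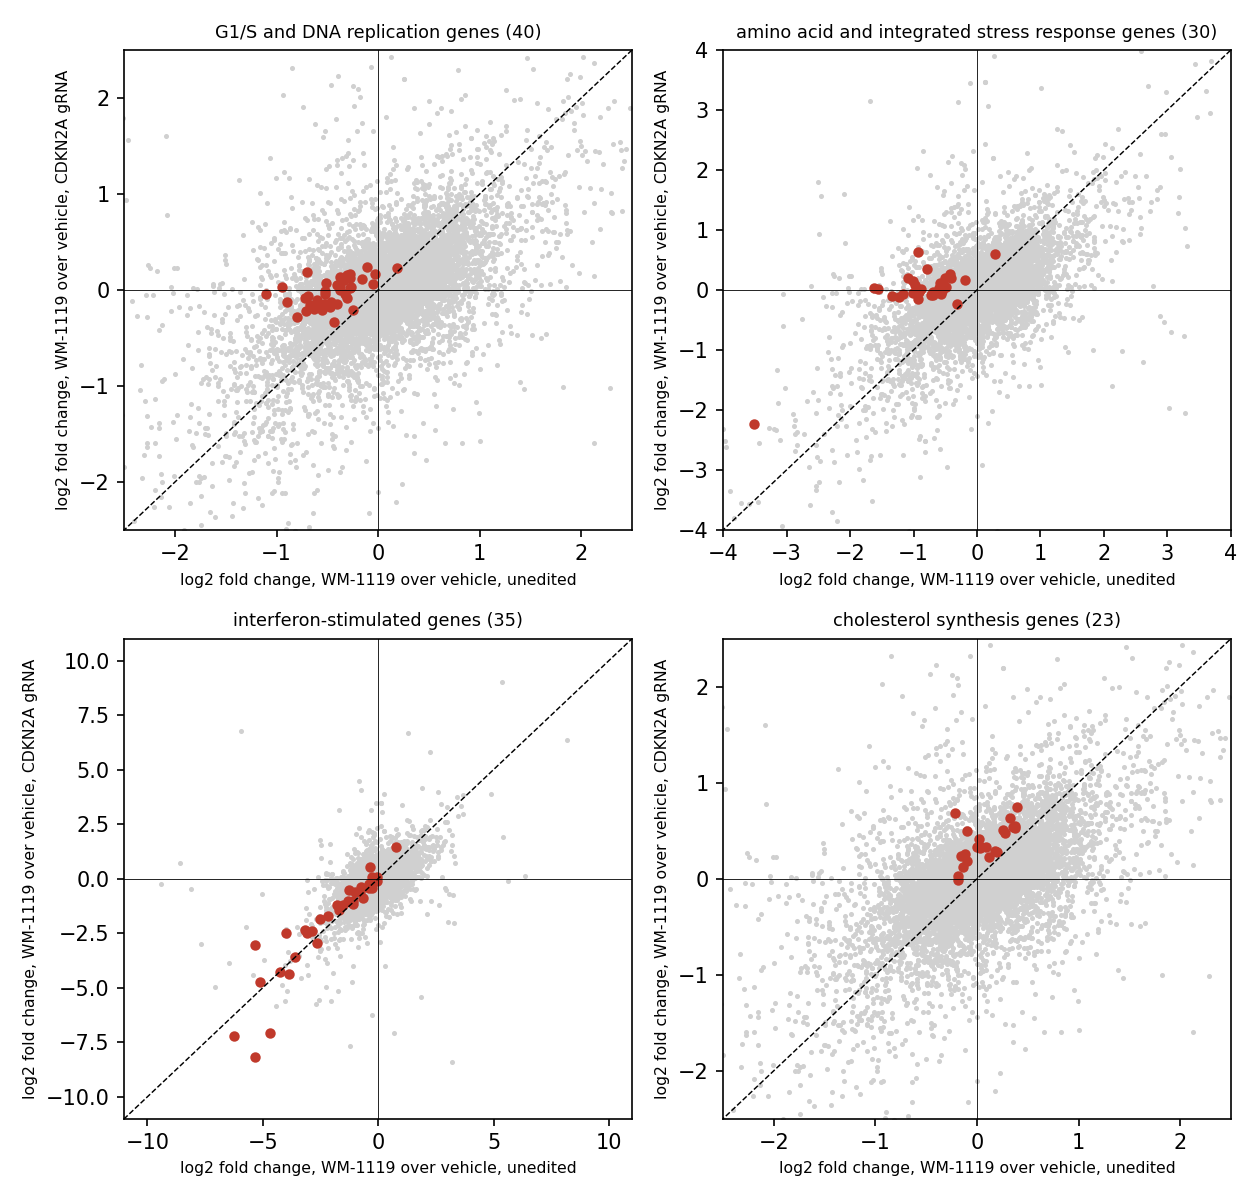
Log2 fold change with WM-1119 in unedited cells (x axis) and in cells labelled CDKN2A gRNA (y axis) for all genes tested (grey) and the members of 4 lists (red, number measured in each title). The dashed line marks equal effects, and grey points beyond the axis limits are not drawn. All 40 G1/S, all 30 amino acid and stress response and all 23 cholesterol synthesis genes lie above the line, as do 24 of the 35 interferon-stimulated genes.

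Whether the response depends on the genotype label was tested as the difference of the 2 WM-1119 effects, gRNA-labelled minus unedited. CDT1 differed by 1.06 ± 0.14 and PRIM1, a primase subunit, by 0.98 ± 0.14. PRIM1 is uncertain because it shares exons with NACA, which has more counts. SHMT2 differed by 0.58 ± 0.08 (adjusted p = 0.0011). S100A8, which went from 10.6 to 104 CPM in unedited cells and from 2.42 to 4.06 CPM in gRNA-labelled ones, differed by -2.59 ± 0.43 (adjusted p = 0.0094). The difference was positive for 377 genes and negative for 296, and for 51 and 36 of them at least 2-fold. Of the 377, 342 fell in unedited cells, 288 of these without a call in gRNA-labelled cells, and of the 296, 245 rose in unedited cells, 190 of these without a call in gRNA-labelled cells.

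The lists given here are only a part of those tested for the difference. By list, the difference was positive in 21 of 40 G1/S genes and negative in 0, with 32 positive when adjusted over the list alone. Their median was 0.43 (camera adjusted p = 4.0e-26, adjusted p = 0.116 with an estimated correlation). RRM2 differed by 0.77 ± 0.12 and CDC45 by 0.63 ± 0.10. Amino acid and stress response genes were positive in 16 of 30 and negative in 0, with 29 when adjusted over the list alone and a median of 0.73 (camera adjusted p = 1.9e-31, adjusted p = 0.122 with an estimated correlation). They included CBS (0.60 ± 0.10), ATF4 itself (0.54 ± 0.09) and SESN2 (0.88 ± 0.15). DNA repair and checkpoint genes were positive in 10 of 30 and negative in 0, with 19 when adjusted over the list alone (camera adjusted p = 4.6e-11, adjusted p = 0.116 with an estimated correlation). CHEK1 differed by 0.55 ± 0.10, which is uncertain because it shares exons with STT3A, which has more counts. Cholesterol synthesis genes were positive in 3 of 23, with 11 when adjusted over the list alone (camera adjusted p = 2.9e-09, adjusted p = 0.177 with an estimated correlation). Neutrophil granule genes were negative in 4 of 13, with 9 when adjusted over the list alone (camera adjusted p = 1.4e-07, adjusted p = 0.197 with an estimated correlation), led by ELANE (-0.60 ± 0.10) and AZU1 (-0.67 ± 0.12). BCL2 differed by 0.54 ± 0.09, PMAIP1 by 1.00 ± 0.16 and BNIP3 by 0.54 ± 0.09, whereas CDKN2A (0.32 ± 0.14, adjusted p = 0.21) did not pass.

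These counts depended on single libraries more than those of the effects within a genotype. With each of the 12 libraries left out in turn, positive genes numbered 139 (without the unedited vehicle replicate 2) to 827 (without the gRNA-labelled vehicle replicate 3) and negative genes 85 and 636 without the same libraries. The G1/S count ran from 7 to 27 and moved by more than 1.5-fold in 7 of the 12 fits. The stress response count ran from 8 to 27 and moved in 8 fits, the DNA repair count from 4 to 17 in 6 fits and the granule count from 3 to 8 in 2 fits. The cholesterol synthesis count ran from 2 to 7 and moved in 2 fits, and was 1 without both the unedited WM-1119 replicate 3 and the gRNA-labelled WM-1119 replicate 2. The median of the G1/S list stayed between 0.33 and 0.46. S100A8 lost its call without the gRNA-labelled vehicle replicate 1 (adjusted p = 0.062, against 3.8e-13 to 0.062 over all alternatives).

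Between genotypes under vehicle, 28 of 35 interferon-stimulated genes were lower and GATA2 was higher in libraries labelled CDKN2A gRNA, with the direction resting on the genotype labels alone. No library with a control guide was analysed here. Differences between genotypes, here and under WM-1119, therefore could not be separated from editing itself or from the history of the edited cultures. GATA2, a transcription factor of blood progenitors and mast cells, was 5.35-fold higher (2.42 ± 0.11), the synaptotagmin-like gene SYTL1 7.24-fold (2.86 ± 0.20) and the potassium channel gene KCNN4 5.80-fold higher (2.54 ± 0.16). LYZ was lower by 2.33-fold (-1.22 ± 0.07) and S100A8 by 4.29-fold (-2.10 ± 0.30). In all, 217 genes were higher and 326 lower, 35 and 63 of them at least 2-fold. Interferon-stimulated genes were lower in 28 of 35 and higher in 0, with 32 lower when adjusted over the list alone and a median of -0.79 (camera adjusted p = 1.1e-61, adjusted p = 0.0041 with an estimated correlation). OAS2 (-1.44 ± 0.13) and IFI6 (-1.46 ± 0.13) were among them. Without the unedited vehicle replicate 2 or the gRNA-labelled vehicle replicate 2, 18 were lower.

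Monocyte and macrophage maturation genes were lower in 8 of 35 and higher in 0 under vehicle in the gRNA-labelled libraries, or 17 and 1 when adjusted over the list alone (camera adjusted p = 1.1e-13, adjusted p = 0.151 with an estimated correlation). They included the ficolin FCN1 (-1.79 ± 0.25) and the oxidase subunit NCF1 (-0.60 ± 0.08). That count was 5 when any 1 of the 3 unedited vehicle libraries was left out. It was 4 without the gRNA-labelled vehicle replicate 2 or replicate 3. The cell adhesion gene ALCAM (1.28 ± 0.10), the transcription factor genes WT1 (1.22 ± 0.20) and JUN (1.08 ± 0.17), the CDK inhibitor CDKN2C (0.83 ± 0.10) and the granule protease PRTN3 (1.08 ± 0.10) were higher. G1/S genes were higher in 4 of 40 and lower in 0, with 10 when adjusted over the list alone (camera adjusted p = 1.5e-09, adjusted p = 0.296 with an estimated correlation). That count ran from 0 without the gRNA-labelled vehicle replicate 2 to 9 without the gRNA-labelled vehicle replicate 1, moving by more than 1.5-fold in 8 of 12 fits. Likewise the genes higher and lower numbered 74 and 124 without the gRNA-labelled vehicle replicate 2 and 548 and 527 without the gRNA-labelled vehicle replicate 1. On the genes that parted the vehicle groups without it, that last library lay midway between them (median position 0.47 from 0, unedited, to 1, gRNA-labelled).

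Under WM-1119 the genotypes differed in 5740 genes, 2900 higher and 2840 lower in the gRNA-labelled libraries, 247 and 380 of them at least 2-fold. CDT1 was 2.72-fold higher (1.45 ± 0.10), the glycolytic enzyme gene ENO2 3.31-fold (1.72 ± 0.15), SYTL1 8.01-fold (3.00 ± 0.15) and GATA2 6.97-fold (2.80 ± 0.11). S100A8 was 25.8-fold lower (-4.69 ± 0.23) and S100A9 12.04-fold lower (-3.59 ± 0.26). The hexokinase HK3 (-2.96 ± 0.12) and FCN1 (-2.75 ± 0.24) were lower. The transcription factor KLF2 (2.49 ± 0.37), the glucocorticoid-induced gene TSC22D3 (1.95 ± 0.19), CDKN1A (0.94 ± 0.15), BCL2 (0.76 ± 0.06), PMAIP1 (0.98 ± 0.11), BBC3 (0.76 ± 0.12) and MYC (0.73 ± 0.08) were higher. KAT6A (0.43 ± 0.09) and KAT7 (0.37 ± 0.06) were also higher.

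In this comparison under WM-1119, G1/S genes were higher in 37 of 40 and lower in 0 in gRNA-labelled libraries, also when adjusted over the list alone (camera adjusted p = 1.4e-27, adjusted p = 0.104 with an estimated correlation). G2/M genes were higher in 22 of 35, with 24 when adjusted over the list alone (camera adjusted p = 4.2e-06, adjusted p = 0.286 with an estimated correlation). DNA repair genes were higher in 21 of 30 and lower in 1, or 22 and 1 when adjusted over the list alone (camera adjusted p = 9.6e-14, adjusted p = 0.094 with an estimated correlation). Amino acid and stress response genes were higher in 29 of 30, also when adjusted over the list alone, with AARS at 0.76 ± 0.09 (camera adjusted p = 2.9e-17, adjusted p = 0.239 with an estimated correlation). Cholesterol synthesis genes were higher in 18 of 23, or 19 when adjusted over the list alone, with HMGCS1 at 1.08 ± 0.11 (camera adjusted p = 3.1e-10, adjusted p = 0.192 with an estimated correlation). Glycolysis and hypoxia genes were higher in 18 of 27 and lower in 1, or 20 and 1 when adjusted over the list alone (camera adjusted p = 4.6e-08, adjusted p = 0.251 with an estimated correlation). NF-kB and immediate early genes were higher in 19 of 32 and lower in 4, or 23 and 4 when adjusted over the list alone (camera adjusted p = 2.4e-04, adjusted p = 0.251 with an estimated correlation). The 4 lower ones were 2 without the unedited WM-1119 replicate 1 or the gRNA-labelled WM-1119 replicate 3.

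Monocyte genes were lower in 19 of 35 and higher in 2 under WM-1119 in the gRNA-labelled libraries, or 20 and 2 when adjusted over the list alone (camera adjusted p = 1.2e-08, adjusted p = 0.239 with an estimated correlation). Granule genes were lower in 10 of 13 and higher in 1, or 10 and 2 when adjusted over the list alone (camera adjusted p = 8.9e-05, adjusted p = 0.251 with an estimated correlation), for example AZU1 (-0.82 ± 0.09) and CTSG (-0.78 ± 0.11). Interferon-stimulated genes were lower in 19 of 35 and higher in 0, or 20 lower when adjusted over the list alone (camera adjusted p = 8.9e-05, adjusted p = 0.251 with an estimated correlation). BST2 was at -0.63 ± 0.08, and the list's median was -0.48, or -0.37 without 3 members at or under the floor in both groups. HOX and MEIS1 genes were lower in 12 of 20 and higher in 0, also when adjusted over the list alone (camera adjusted p = 0.0060, adjusted p = 0.507 with an estimated correlation), with HOXB3 at -0.67 ± 0.12. Without the gRNA-labelled WM-1119 replicate 1, 7 of them were lower. All 13 mitochondrially encoded genes were lower, also when adjusted over the list alone (camera adjusted p = 2.5e-05, adjusted p = 0.343 with an estimated correlation). Of 31 nuclear respiratory chain genes 18 were lower and 2 higher, also when adjusted over the list alone (camera adjusted p = 7.9e-04, adjusted p = 0.239 with an estimated correlation). The mitochondrial share of counts was 5.79 to 7.21% in the gRNA-labelled libraries and 7.84 to 10.01% in the unedited ones. The effect of the genotype label under vehicle and under WM-1119, which share no library, correlated across genes with r = 0.475 and rho = 0.572.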

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

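In this part, the test with all libraries thinned to the smallest total and the fit without 2 doubted libraries were chosen after the results were seen. The results below were singled out because the effect of WM-1119 was tested to differ between cells labelled CDKN2A gRNA and unedited cells. The difference (gRNA-labelled minus unedited) was positive for 377 genes and negative for 296, and its median was 0.43 for G1/S and DNA replication genes, 0.73 for amino acid and integrated stress response genes, 0.33 for DNA repair and checkpoint genes and -0.60 for neutrophil granule genes. These directions rest on the genotype labels alone.

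Among single genes, the log2 difference was 0.98 for PRIM1 (uncertain, since it shares exons with NACA), 1.06 for CDT1, 0.63 for CDC45 and 0.77 for RRM2 in the G1/S list, and 0.55 for CHEK1, 0.67 for BARD1 and 0.50 for XRCC2 in the repair list. It was 0.58 for SHMT2, 0.60 for CBS, 0.54 for ATF4, 0.49 for GPT2 and 0.88 for SESN2 in the amino acid and stress response list, 0.59 for INSIG1 and 0.90 for HMGCS1 in the sterol list, and 0.54 for BNIP3 and 1.32 for ENO2 in the glycolysis list. Granule and monocyte genes had negative values: ELANE -0.60, AZU1 -0.67, PRTN3 -0.76, TYROBP -1.01 and S100A8 -2.59. PMAIP1 (1.00), BCL2 (0.54), DCK (0.69) and CDKN1A (0.84) had positive ones. RRM2, CHEK1, SHMT2, HMGCS1 and DCK also share exons with another gene tested and are uncertain in that respect. CHEK1 had a mean of 50.5 CPM, below its partner STT3A (151 CPM), and DCK 48.7 CPM, near MOB1B (43.2 CPM). Outside the lists, the difference was for example 1.66 for NEXN, 1.64 for SPTB, which is uncertain because it overlaps PLEKHG3, -1.83 for CRISPLD2, -1.67 for PDE3A, -1.64 for FUCA1 and -1.57 for KCNN4. Of 100 genes named for the effects of WM-1119 within a genotype, 29 had this difference past the threshold.

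The adjusted p of TYROBP was 0.051 without the unedited vehicle replicate 2 (0.0011 to 0.054 over all alternatives), and that of S100A8 was 0.062 without the gRNA-labelled vehicle replicate 1 (3.8e-13 to 0.062). That of CDKN1A was above 0.05 in 8 of the 12 fits with 1 library left out and was highest, 0.105, without the gRNA-labelled WM-1119 replicate 1 (0.0084 to 0.137). Without both doubted libraries, HMGCS1, PRTN3, TYROBP and SESN2 also lost their calls. The other single genes above kept their calls under all alternatives in which they were tested.

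The smaller response of G1/S genes in gRNA-labelled cells was weighed as a technical effect. Its median difference of 0.43 was 0.41 after every library was thinned to the smallest total, which argues against depth, and 0.33 at the lowest (without the unedited WM-1119 replicate 1) when each library was left out, which argues against a single library. After a trend over GC content and transcript length was subtracted it was 0.44 for all 40 genes, which argues against such a bias, though that step moved most genes little (median absolute shift 0.0524, largest 0.36). The genotype named by the labels thus stays a candidate explanation, as a hypothesis found in these data. It could not be separated from the history of the edited cultures, since no library with a control guide was analysed here.

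Other splits of the same libraries show how far grouping by chance can be judged. With 3 against 3 libraries, 10 splits are too few for a share under 0.05; the real counts of genes past the threshold and the highest of the other splits were 5237 and 0 for WM-1119 in unedited cells, 2601 and 2 in gRNA-labelled cells, 543 and 1 for the genotypes under vehicle and 5740 and 0 under WM-1119, and in each case 1 split, the real one, reached that count. Every other split of that kind mixes the groups compared, so their real difference enters the spread within groups and lowers the count. Those low counts therefore do not show what chance would give. For the difference of effects, 7 of 100 drawn splits gave as many genes as the real one (673), with 3877 the highest. The 6 others were the 6 drawn splits that part the WM-1119 libraries by genotype and mix the vehicle libraries. The highest of the remaining splits was 1. Splits that mix only the vehicle libraries turn the genotype contrast under WM-1119 into a difference of effects. The share of 7 in 100 therefore cannot judge chance for that count, and chance is not excluded.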

How the results depend on the processing

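In this part, the thinned libraries and the fit without 2 doubted libraries were chosen after seeing the data. No called result of a named gene changed direction under any alternative. Set tests were rerun only with an estimated correlation, fry, the replicate block and DESeq2 factors, not with libraries left out or thinned. In those reruns no called set test changed direction, which an estimated correlation cannot change in camera. Counts of genes that rose and fell with WM-1119 stayed within 1.5 times the reported ones under every alternative in unedited cells (1968 to 2714 and 2141 to 2903) and gRNA-labelled cells (871 to 1334 and 960 to 1461), as did those between genotypes under WM-1119 (1990 to 3110 and 1952 to 3008). CDKN2A stayed between 0.56 and 0.67 (log2) for the genotypes under vehicle and between 1.01 and 1.23 for WM-1119 in unedited cells.

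The counts for the difference of effects moved most. Against 377 positive and 296 negative genes, the DESeq2 Wald test gave 447 negative ones, and the fit without both doubted libraries gave 120 and 86; that fit has fewer libraries, and the cause was not tested further. With 1 library left out, positive genes ran from 139 (without the unedited vehicle replicate 2) to 827 (without the gRNA-labelled vehicle replicate 3) and moved by more than 1.5-fold in 9 of 12 fits, and negative genes ran from 85 to 636 without the same libraries and moved in 10 of 12. Between genotypes under vehicle, against 217 higher and 326 lower genes, the counts ran from 74 and 124 (without the gRNA-labelled vehicle replicate 2) to 548 and 527 (without the gRNA-labelled vehicle replicate 1), moving in 8 and 6 of 12 fits. The correlation of the 2 WM-1119 effects, 0.583, ran from 0.479 (without the gRNA-labelled WM-1119 replicate 3) to 0.584 (without the unedited WM-1119 replicate 3). The cause of these moves was not tested.

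With the replicate number as a block, the difference counts were 242 positive and 155 negative, and 120 genes were higher in gRNA-labelled libraries under vehicle. The G1/S count for the difference was 13 in place of 21, and that for the genotypes under vehicle 2 in place of 4. CDKN1A in the difference and MYC under vehicle (not reported above) lost their calls, 1 set test gained one, and no other call of a named gene or list changed. The numbers did not pair the libraries across all groups. Correlations of same-numbered libraries ran from -0.226 to 0.196 over 18 pairs, 3 of them above 0.1. Of 12 libraries, 0 correlated best with their own number in every other group. Within a treatment, however, pairs of replicates 1 and 3 were all positive (0.078 to 0.196), and those of replicate 2 were near 0 (-0.032 and -0.003). Between treatments, pairs of replicates 1 and 3 were all negative (-0.226 to -0.041). A block common to both treatments cannot absorb such a pattern. Structure shared by number within a treatment thus stays open. The CDKN1A difference stayed at 0.84, MYC under vehicle at 0.34 and the G1/S medians for the 2 contrasts at 0.43 and 0.16.

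Of 301 results for named genes, 265 passed the threshold, and 17 of these lost their call under at least 1 alternative, 12 of them when 1 library was left out. Of 140 set tests, 66 lost their call with an estimated correlation, 16 lost and 13 gained one with fry, and 1 lost it with DESeq2 factors. For the difference, the amino acid and stress response count was 26 with the DESeq2 Wald test or without the robust option and 6 without both doubted libraries, against 16, and the granule count was 8 with the DESeq2 test and 2 without both doubted libraries, against 4. For WM-1119 in unedited cells, 6 mitochondrially encoded genes rose and 2 ribosomal protein genes fell without both doubted libraries, against 13 and 7. For the genotypes under WM-1119, that fit gave 7 lower mitochondrially encoded genes against 13, 11 nuclear respiratory chain genes against 18, 6 HOX and MEIS1 genes against 12, and 12 higher NF-kB genes against 19. Depth limits the genes near 0, where a single count is up to 0.0969 CPM.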

Other observations

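In this part, the tests of reads shared with CDKN2B and of exchanged genotype labels, the position of single vehicle libraries and the comparison of histone genes were chosen after the result was seen. CDKN2A mRNA was higher, not lower, in libraries labelled CDKN2A gRNA. The level of its neighbour CDKN2B, 1.53 to 2.25 CPM in the unedited vehicle libraries, argues against a shift of reads from it. Under vehicle CDKN2A was at 22.9 to 26.5 CPM in unedited and 36.8 to 38.2 CPM in gRNA-labelled libraries, a larger gap. The sum of both genes was higher by 0.59 ± 0.05 (log2) under vehicle, which mostly restates CDKN2A. CDKN2B itself went from 1.96 to 2.40 CPM. By correlation over all genes tested, 1 of the 12 libraries, the gRNA-labelled vehicle replicate 1, was closest to a library of another group, an unedited vehicle one (0.988 against 0.987 within its group), which a wrong label would give. Without it CDKN2A was still higher by 0.63 (adjusted p = 0.0094), which argues against that library as the source of the higher values. Of the 1071 genes that parted the vehicle groups when it was left out, 517 (48.3%) put it on the side of its own group, with a median position of 0.47 from 0 (the other group) to 1 (its own). For each of the other 5 vehicle libraries, left out in the same way, this was 91.8 to 97.2% and 0.86 to 1.04. Those fits gave only 197 to 237 genes. They held the gRNA-labelled vehicle replicate 1, which favours genes on which it lies with its group, so the comparison is uneven. On the second principal component, an axis of spread between libraries, replicates 1 to 3 of that group lay at 8.57, -3.81 and -13.0. The unedited vehicle libraries lay at 16.8 to 26.4. That group was thus graded, without a single library set apart from like ones. On the 1071 genes, the gRNA-labelled vehicle replicate 1 lay midway between the groups. A plain wrong label would put it near 0, so this argues against one. Its CDKN2A, GATA2 and LYZ (36.8, 17.8 and 631 CPM) lay near its own replicates (37.6 and 38.2, 19.9 and 18.5, 537 and 572 CPM). The unedited vehicle libraries held 22.9 to 26.5, 3.15 to 3.82 and 1305 to 1420 CPM. For these genes, the values also argue against a mixture in even shares, which would put them between the groups. A culture that differed stays open and was not tested. An exchange of the genotype names of all libraries cannot be told apart from the labels as given, since the log2 value of 0.61 would only take the other sign and no DNA was read; a higher transcript in edited cells stays open as a biological explanation that was not tested.

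The gRNA-labelled WM-1119 replicate 2 stood apart in RNAs that carry no poly(A) tail. The 3 entries FP236383.3, FP671120.3 and FP236383.2, which have identical values, made up 3.5% of its counts, against 0.0842 to 0.164% in the other libraries, and RMRP was at 46.2 CPM against 1.21 to 2.92. The 12 genes of the HIST clusters had a median log2 ratio to its 2 replicates that lay 1.76 above that of 6 histone genes with polyadenylated mRNA, and all 12 were higher than in both replicates. These genes are part of the pattern itself, so this describes it and does not test carry-over of such RNA, which stays open. More cells in S phase would raise G1/S genes too, but their median log2 ratio was -0.0085 ± 0.0127, which argues against it; this SE is from a bootstrap over genes for 1 library against its 2 replicates and holds no spread between libraries. No biological explanation beyond this was tested.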
